A study of Homo sapiens with 2 samples.

How the data were processed

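Small RNA bound to MBP-MCP amylose resin or to bare amylose resin was profiled by miRNA sequencing in BT549 cells that overexpress MS2-tagged SNHG15. RNA was extracted with the mirVana kit and libraries were made with the QIAseq miRNA kit, per the labels' protocols. Each group held 1 library, grouped by the resin treatment in the labels, so the groups share no replicate pairs. Genome build GRCh38 is named per the submitters' processing notes. The aligner, the miRNA annotation release and the handling of molecular identifiers are not given in the sources used here.

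The authors deposited a table of raw read counts of 407 miRNAs in both libraries, in whole numbers, and the lowest sum of a miRNA over both libraries was 2. Of these miRNAs, 357 carry miRNA names and 50 are numbered predictions, with no sequence or position used here; these are described by their reads. Their reads, 1.56% of the pulldown library and 1.93% of the control library, stayed in the totals. The same table gives a value the authors' header calls Tpm, which equals reads per 1000000 reads of the library (RPM), with no length term. The log2 fold change in the authors' deposited table is the log2 ratio of those values, with no further normalisation, and is infinite where a value is 0. The p-values and adjusted p-values are the authors', and the dispersion behind them is not stated per the file headers. Those p-values were recomputed from the counts by edgeR's exact test with TMM factors (0.935 for the pulldown, 1.07 for the control) and a fixed biological coefficient of variation (BCV) of 0.1, with a largest difference of 6.11e-15 in log10 p. That recipe was found by trying settings on the deposited values. The 3 lists of called miRNAs that the authors deposited are subsets of the table. There were 0 columns of other samples.

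From the counts, the ratio of RPM in the pulldown to that in the control was computed for each miRNA, scaled by total reads. log2 ratios carry a prior count of 0.5 scaled by library size. The 95% interval of a ratio is the exact conditional binomial (Clopper-Pearson) interval of its read numbers. A value of 0 was set to 3 reads for a bound where the other library had more than 3. That of a predicted miRNA, whose lowest value above 0 was 10, was set to 10 as an alternative. With 1 library per group no p-value for a difference between the conditions was computed, and a rule of size was used instead, at least 2-fold among miRNAs with at least 20 reads in a library. In all, 249 miRNAs in the pulldown and 273 in the control had fewer than 20 reads.

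The median log2 ratio of each of 26 lists was computed over its measured members, 25 lists having any. It was placed among 10000 random lists of the same size, each member drawn from the 20 miRNAs nearest in mean expression. The lists were the let-7, miR-17-92, miR-15/16, miR-23/27/24, miR-29, miR-30, miR-99, miR-100 and miR-125, miR-26, miR-181, miR-221 and miR-222, miR-130, miR-301 and miR-454, miR-148 and miR-152, miR-103 and miR-107, miR-320 and miR-34 and miR-449 families or clusters, epithelial, mesenchymal, erythroid, leukocyte, liver, muscle and neuronal markers, the 14q32 and C19MC clusters, doubtful or non-canonical entries, and miRNAs named elsewhere as SNHG15 partners. The miRNAs named in the text were the 12 with the largest excess and the 12 with the largest deficit among those with 20 reads, the 5 most abundant of each library, up to 4 of the most abundant members of each list and all measured SNHG15 partners. Others, among them the authors' called miRNAs, miR-17-5p and miR-132-3p, were named after their values were seen. The groups, the lists, the seeds, the rule for names, the ratio, the thresholds and most of the other settings tried were fixed before the data were examined.

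Alternatives were TMM factors, DESeq2 median-of-ratios size factors, totals without the 5 most abundant miRNAs, a prior count of 5, other read minimums, a 4-fold threshold, a 2-fold bound for the whole interval, predicted miRNAs at 0 set to 10 reads, and stricter calls from the deposited table. Seeds, nucleotides 2 to 8 of 143 measured miRNAs, were searched as 7-base matches in transcript SNHG15-203 of GENCODE 29, 982 bases long, 1 of 10 annotated transcripts. The isoform in the construct is not given in the sources used here. GC content was taken over the side of the hairpin that holds the miRNA, or over the whole hairpin where the name gives no arm. It was averaged where a miRNA has several hairpins. Positions come from GENCODE 29 on GRCh38.

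The steps were tested on simulated data, 50 simulations of the pulldown against the control over 407 miRNAs with 200 changed. Intervals covered the true ratio in 96.0% of cases. The rule of size picked 50.9% of true 2-fold changes, 99.5% of true 4-fold changes and 1.27% of unchanged miRNAs. For these rates the simulated log2 ratios were first corrected by the known change in composition, which was not done for the real ones. The simulated counts held counting error alone, so the rates need not hold for these libraries. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.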

Results

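BT549, an established human breast cancer cell line, was used in a form that overexpresses the long non-coding RNA SNHG15 tagged with MS2 hairpins. MS2 hairpins are short RNA loops from a bacteriophage that the MS2 coat protein (MCP) binds. Lysate was incubated with amylose resin carrying MCP fused to maltose binding protein (MBP), or with bare amylose resin, and the small RNA that stayed on the resin was sequenced. The comparison asks which miRNAs associate with SNHG15, but the resins also differ in the MBP-MCP protein itself. No library came from MBP-MCP resin without tagged SNHG15. RNA held by that protein therefore cannot be told apart from RNA held through SNHG15. There was 1 library for each resin, so no difference has a replicate check, and nothing in the labels says whether the lysates came from separate cultures. The pulldown library held 202560 miRNA reads and the control library 111414, a ratio of 1.82. Of the 407 miRNAs in the count table, 377 had reads in the pulldown library and 349 in the control library, with medians of 12 and 8 reads. SNHG15 lies on chromosome 7, from 44983023 to 44986961 on the minus strand of GRCh38, and is annotated as a lincRNA. Its own level in the pulldown was not analysed here.

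The same miRNAs dominated both libraries. miR-16-5p, which represses BCL2 and cyclins, was the most abundant, with 34274 reads in the pulldown library and 17015 in the control library, 1.11-fold higher in the pulldown in reads scaled to the library total (RPM; 95% interval 1.09 to 1.13). let-7a-5p, of the let-7 family that LIN28 blocks, had 30194 and 16371 reads and a ratio of 1.01 (0.995 to 1.03). let-7i-5p had 26463 and 14499 reads (ratio 1.0, 0.984 to 1.02), and let-7f-5p had 21176 and 11536 (ratio 1.01, 0.987 to 1.03). let-7b-5p stood higher in the pulldown library, with 14131 against 6248 reads and a ratio of 1.24 (1.21 to 1.28). miR-125b-5p stood lower, with 10378 against 6539 reads and a ratio of 0.873 (0.846 to 0.901), but its log2 ratio of −0.20 turned to 0.081 with DESeq2 size factors. The 4 most abundant miRNAs made up 55.3% of the pulldown reads and 53.3% of the control reads, and the 10 most abundant 77.6% and 75.7%. Intervals are exact Clopper-Pearson intervals and cover counting error only.

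**Figure D1:**
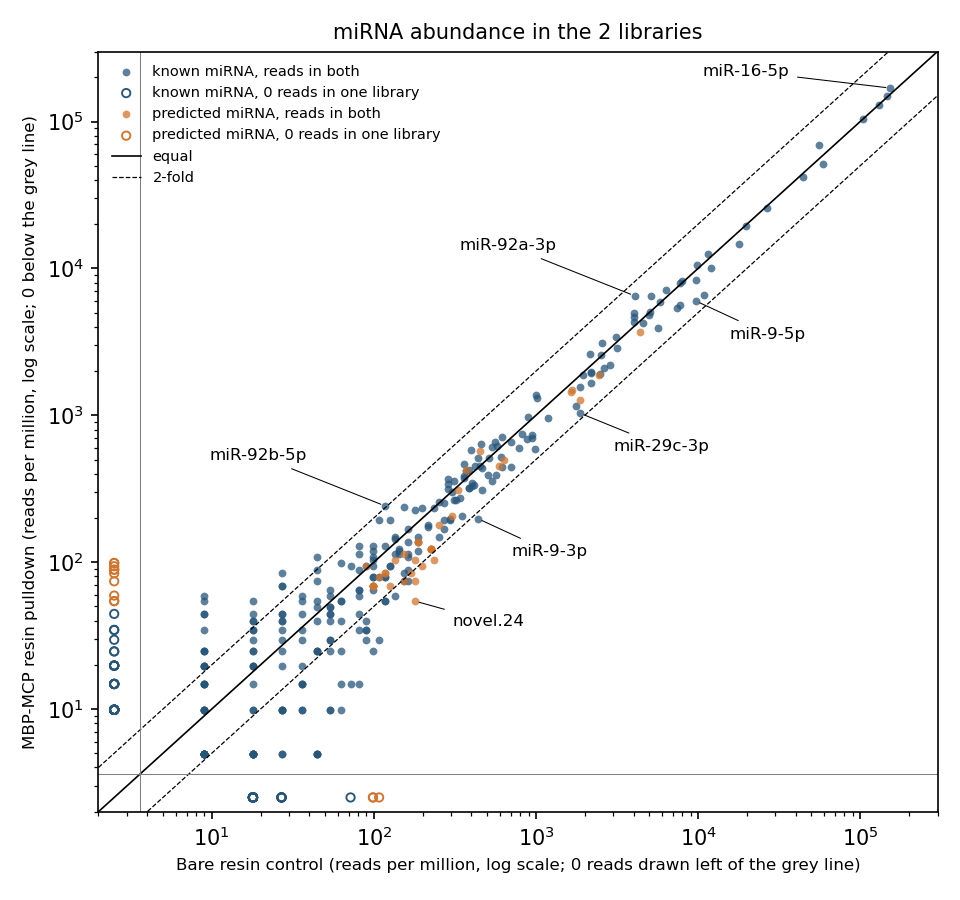
RPM of each of the 407 miRNAs in the bare resin control (horizontal, log scale) and in the MBP-MCP pulldown (vertical, log scale); filled points had reads in both libraries, open points lie at 0 reads in one of them, and predicted miRNAs are orange. Of the 161 miRNAs with at least 20 reads in a library, 94.4% lie between the dashed 2-fold lines.

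Among 161 miRNAs with at least 20 reads in a library, 133 known and 28 predicted, the RPM values of the libraries correlated across miRNAs with a Spearman coefficient of 0.967 and a Pearson coefficient of 0.946 on the log2 scale; miRNAs are not independent replicates. The ratio was within 1.5-fold for 128 (79.5%) and within 2-fold for 94.4%. Of the 105 miRNAs with at least 50 reads in a library, 0 reached 2-fold. The median log2 ratio was −0.16, a shift that depends on scaling: TMM factors raised it by 0.20, DESeq2 size factors by 0.28, and totals without the 5 most abundant miRNAs by 0.11. The ratios compare shares of a library, and no measure of the amount of RNA on each resin was used here. A lower share therefore does not show that the MBP-MCP resin held less of a miRNA than the bare resin. Intervals excluded equality for 56 miRNAs (34.8%, against 5% from counting error alone), 18 higher and 38 lower in the pulldown. This split became 36 and 15 with TMM factors and 44 and 12 with DESeq2 size factors. The DESeq2 factors, 1.22 for the pulldown and 0.816 for the control, are medians over all miRNAs with reads in both libraries, also those under 20 reads. Set against the median of all 161, 31 intervals lay above it and 18 below. Known miRNAs with at least 60 reads in all had a higher median log2 ratio, −0.06. Numbers above and below the median of all miRNAs, here and in the families, therefore depend on that choice of reference.

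miR-92a-3p, the member of the miR-17-92 cluster that restrains blood vessel growth, had the largest excess in the pulldown among miRNAs with 50 or more reads. It had 1319 against 452 reads, a log2 ratio of 0.68 and a ratio of 1.61 (1.44 to 1.79). Its hairpins are MIR92A1 on chromosome 13, from 91351314 to 91351391 on the plus strand inside MIR17HG, and MIR92A2 on chromosome X, from 134169538 to 134169612 on the minus strand. By the rule of 2-fold with 20 reads, 4 miRNAs were higher in the pulldown, 2 of them known. miR-92b-5p had 49 against 13 reads, a ratio of 2.07 (1.11 to 4.17); MIR92B lies on chromosome 1, from 155195177 to 155195272 on the plus strand. miR-27a-5p had 22 against 5 reads, a ratio of 2.42 whose interval of 0.894 to 8.18 includes 1. With a prior count of 5 both fell under 2-fold, to log2 ratios of 0.88 and 0.87. The other two were predicted miRNAs with 20 reads in the pulldown and a control value of 0. No predicted miRNA had a value from 1 to 9 reads in either library, so their 0 need not be a true 0; with 10 control reads the ratio would be 1.10, and with 9 its interval would include 1.

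The remaining known miRNAs among the 12 with the largest excess were below 2-fold with total reads; miR-374a-5p, with a log2 ratio of 0.82, passed it with TMM factors (1.01) and DESeq2 size factors (1.10). miR-181a-2-3p had 117 against 44 reads (ratio 1.46, 1.03 to 2.12) and miR-1307-3p had 130 against 51 (ratio 1.40, 1.01 to 1.98). The intervals of miR-374a-5p (39 against 12 reads, ratio 1.79), miR-92b-3p (26 against 9, ratio 1.59), miR-25-5p (20 against 7, ratio 1.57), miR-197-3p (48 against 17, ratio 1.55) and miR-140-3p (39 against 14, ratio 1.53) all included 1. Of these, only that of miR-374a-5p lay above the median of all miRNAs. Its lower bound of 0.917 did not pass 0.962, the median ratio of known miRNAs with at least 60 reads in all.

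On the other side, miR-9-3p, made from the hairpins that also give the brain-enriched miR-9-5p, was the known miRNA with the largest deficit in the pulldown among those with at least 20 reads in a library. It had 40 against 49 reads and was 2.23-fold lower (1.44 to 3.47), with a log2 ratio of −1.14 that became −0.95 with TMM factors and −0.87 with DESeq2 size factors, under 2-fold. Its hairpins are MIR9-1 on chromosome 1 (156420341 to 156420429, minus strand, within C1orf61), MIR9-2 on chromosome 5 (88666853 to 88666939, minus strand, within LINC00461) and MIR9-3 on chromosome 15 (89368017 to 89368106, plus strand, within MIR9-3HG). miR-29c-3p, of a family that represses collagen genes, had 209 reads in each library and was 1.82-fold lower in RPM (1.49 to 2.21). MIR29C lies on chromosome 1, from 207801852 to 207801939 on the minus strand, within MIR29B2CHG. The other 4 miRNAs at least 2-fold lower were predicted ones, with 11 against 20, 15 against 20, 21 against 26 and 19 against 22 reads, and were 3.31-fold (1.51 to 7.64), 2.42-fold (1.18 to 5.09), 2.25-fold (1.22 to 4.21) and 2.11-fold (1.09 to 4.11) lower. The last 6 of the 12 largest deficits were also predicted miRNAs, 5 with 25 reads in each library (1.82-fold lower, 1.0 to 3.30) and 1 with 21 against 20 reads. Among the 37 predicted miRNAs with reads in both libraries, 13 fell into 4 groups with identical counts. Without sequences it cannot be told whether these are separate miRNAs, so counts of predicted miRNAs may hold repeats. TMM factors left 5 miRNAs at least 2-fold higher and 2 lower, and DESeq2 size factors 5 and 1, against 4 and 5 with total reads.

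**Figure D2:**
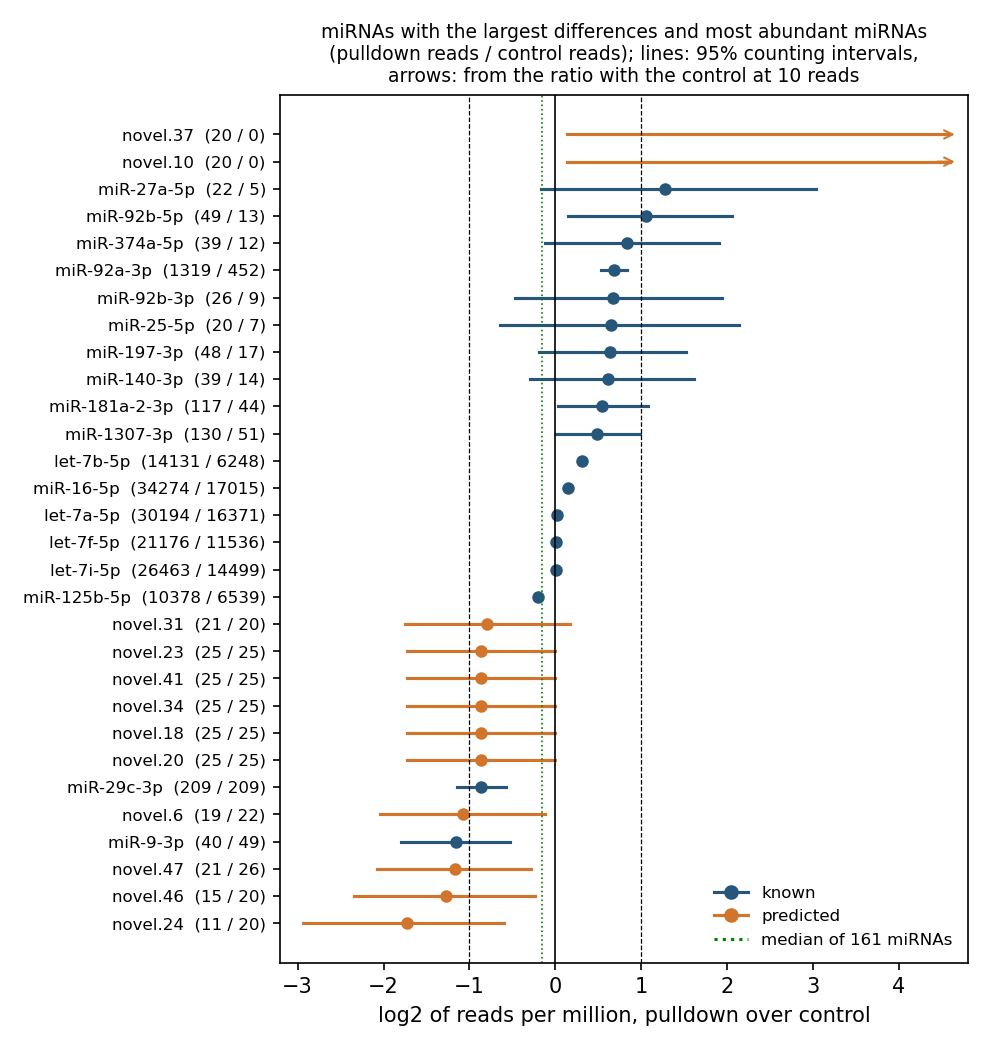
log2 ratio of RPM, pulldown over control, for the miRNAs with the largest excess or deficit and the most abundant ones, with reads in the pulldown and the control in brackets and names as the count table gives them; lines are 95% counting intervals, arrows start at the ratio for a control value of 10 reads, and the dotted line is the median of 161 miRNAs. miR-92a-3p has the narrowest interval among those with the largest excess, from 1.44 to 1.79 as a ratio.

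Families of miRNAs were compared by their median log2 ratio and its percentile among 10000 random lists of like size and abundance, over 23 lists. The random lists could also draw predicted miRNAs, which may shift the percentiles of known families. The let-7 family had 9 measured members, a median of 0.01 (percentile 78.0) and 47.0% of the pulldown reads against 45.3% of the control reads; 7 members lay above the median of all miRNAs. The miR-17-92 cluster with its paralogues, known as an oncogenic miRNA cluster, had a median of 0.16 over 9 members (percentile 99.1). Of these, 7 lay above the median of all miRNAs, 3 by more than counting error: miR-92a-3p, miR-25-3p (1438 against 706 reads, log2 ratio 0.16) and miR-93-5p (3953 against 2195, log2 ratio −0.01). The lower bound of miR-93-5p, 0.940, did not pass 0.962, the median ratio of known miRNAs with at least 60 reads in all. Of the 9 members miR-17-5p was the lowest, with 34 against 30 reads and a log2 ratio of −0.67.

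All 3 measured members of the miR-29 family lay below the median of all miRNAs by more than counting error, and below 0 under every scaling tried. Their log2 ratios were −0.29 for miR-29a-3p, −0.40 for miR-29b-3p and −0.86 for miR-29c-3p, with a list percentile of 6.87. The miR-148 and miR-152 family, which represses DNA methyltransferase genes, was below 0 in all 3 members under every scaling, with a median of −0.75 (percentile 2.25). Of the 3, 2 lay below the median of all miRNAs by more than counting error. miR-152-3p had 119 against 110 reads and was 1.68-fold lower (1.29 to 2.20). miR-148a-3p had only 5 against 11 reads, and with members of 20 reads alone the median was −0.54. In the miR-23/27/24 clusters miR-27a-3p had 1345 against 1219 reads and was 1.65-fold lower (1.52 to 1.78), while miR-23a-3p had a log2 ratio of −0.01. All 5 members of those clusters were below 0 with total reads, 3 with TMM factors and 2 with DESeq2 size factors, and the list's percentile was 12.8.

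Medians of other families were −0.22 for miR-15/16 (percentile 44.2), −0.02 for miR-30 (76.0), 0.04 for miR-99/100 and miR-125 (76.8), 0.02 for miR-26 (62.5), −0.10 for miR-221 and miR-222 (50.3), −0.38 for miR-130, miR-301 and miR-454 (23.2) and 0.17 for miR-103 and miR-107 (89.2). Those of miR-30 and of miR-221 and miR-222 turned positive with TMM factors and with DESeq2 size factors, and that of miR-15/16 with DESeq2 size factors. The miR-181 family had a median of −1.42 (percentile 12.3), or −0.44 with a prior count of 5. Only miR-181a-5p reached 20 reads, with 36 against 24 and a log2 ratio of −0.27. The miR-34 and miR-449 family had 2 measured members and a median of −0.96 (percentile 16.6), or 0.13 with members of 20 reads alone, with miR-34a-5p at 22 against 11 reads and miR-34c-5p at 3 against 8. In the miR-320 family miR-320a had 63 against 52 reads and a log2 ratio of −0.58, while miR-320c and miR-320d had 6 and 4 pulldown reads and 0 control reads; the median was 2.85 (percentile 98.9), or −0.45 with the zeros at their bound of 3 reads. Reads that match more than 1 member of a family, such as let-7 or miR-29, leave its members uncertain, since how the authors assigned them is not given in the sources used here.

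**Figure D3:**
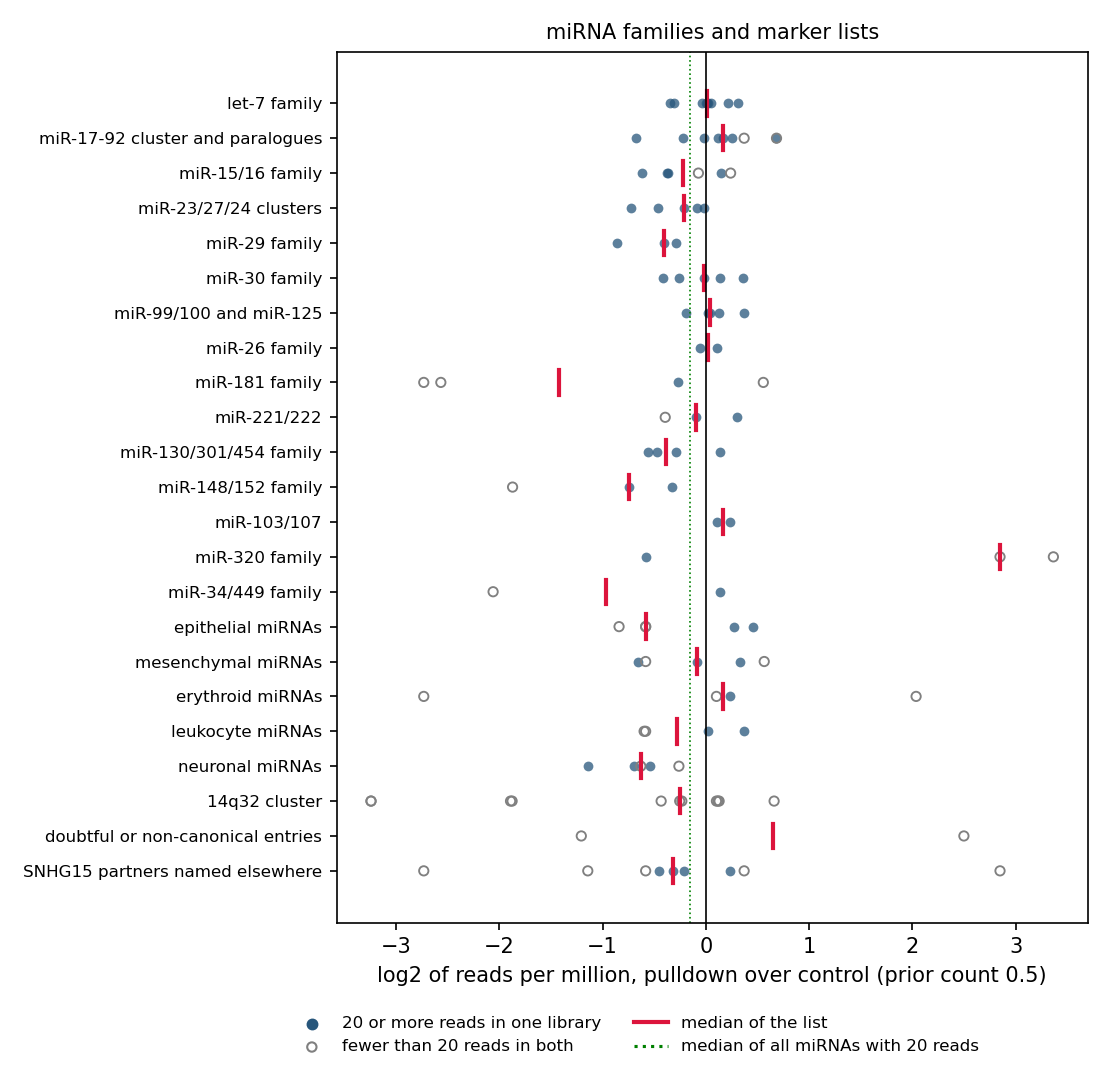
log2 ratio of RPM, pulldown over control, with a prior count of 0.5, for members of the 23 lists with at least 2 measured members; filled points had 20 or more reads in a library, red bars are list medians and the dotted line is the median of the 161 miRNAs. The neuronal list lies wholly below that median, from −1.14 for miR-9-3p to −0.26 for miR-132-3p; with DESeq2 size factors miR-132-3p lies above 0.

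Marker lists of other cell types were compared the same way. The neuronal list stood lowest: all 5 members were below 0 with total reads and TMM factors, and 4 with DESeq2 size factors, where miR-132-3p lay above 0. Its median was −0.63 (percentile 0.720). miR-9-5p had 1215 against 1081 reads and was 1.62-fold lower (1.49 to 1.76), and miR-128-3p had 791 against 632 reads and was 1.45-fold lower (1.31 to 1.61). miR-124-3p had 8 against 7 reads and miR-132-3p 9 against 6, too few to show a difference. miR-9-5p and miR-9-3p come from the same hairpins, so the 5 members are not independent, which the percentile does not take into account. The epithelial list had a median of −0.58 (percentile 7.70), or 0.36 with members of 20 reads alone; miR-183-5p (280 against 112 reads, ratio 1.38, 1.10 to 1.73) and miR-182-5p (529 against 241, ratio 1.21, 1.04 to 1.41) were higher in the pulldown. Among mesenchymal miRNAs (median −0.08, percentile 60.1), miR-10a-5p had 1306 against 571 reads (ratio 1.26, 1.14 to 1.39) and miR-143-3p 90 against 78 (ratio 0.635, 0.463 to 0.871).

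Blood cell markers were mixed. miR-155-5p, of activated lymphocytes, had 265 against 113 reads (ratio 1.29, 1.03 to 1.62), in a leukocyte list with a median of −0.28 (percentile 55.6), or 0.19 with members of 20 reads alone. miR-486-5p led the erythroid list (median 0.17, percentile 39.4) with 133 against 62 reads. The liver miRNA miR-122-5p had 4 against 0 reads and the muscle miRNA miR-1-3p 9 against 1. The 11 measured members of the 14q32 cluster (median −0.25, percentile 43.3) all had fewer than 20 reads, and 0 of 19 listed members of the C19MC cluster were in the table. Doubtful or non-canonical entries had 2 members (median 0.65, percentile 64.1), miR-7641 with 3 against 0 reads and miR-6087 with 2 against 3. Their median fell to 0.028 with a prior count of 5.

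Of 12 miRNAs named elsewhere as SNHG15 partners, 9 were in the table, and none lay above the median of all miRNAs by more than counting error. miR-24-3p had 1692 against 1079 reads (ratio 0.863, 0.799 to 0.932), and its log2 ratio of −0.21 turned to 0.064 with DESeq2 size factors. miR-7-5p had 1139 against 859 (ratio 0.729, 0.667 to 0.798). miR-486-5p had a ratio of 1.18 (0.867 to 1.62), miR-345-5p 0.802 (0.464 to 1.41), miR-18a-5p 1.31 (0.546 to 3.45) and miR-338-3p, with 12 against 15 reads, 0.440 (0.188 to 1.01). miR-200a-3p had 1 read in each library, miR-153-3p 4 against 0 and miR-627-5p 0 against 2, too few to show a difference. The list median was −0.31 (percentile 45.7). It was −0.45 with the 0 of miR-153-3p at its bound of 3 reads and miR-627-5p, with too few reads for a bound, left as it was.

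The authors' deposited table calls 26 miRNAs different, 16 higher and 10 lower in the pulldown, and every one of them has a p-value under 0.05 and a log2 fold change of at least 1 in size. Of these, 14 are predicted miRNAs and 12 are known. Some of the 14 share identical counts and may not be separate miRNAs. The split rests on the scaling: the same test at a coefficient of variation of 0.1 without TMM factors gave 30 calls, 12 higher and 18 lower. Known miRNAs called higher were miR-92b-5p, miR-584-5p (17 against 3 reads), miR-301a-5p (12 against 1), miR-365b-5p (9 against 0), miR-16-2-3p (7 against 0) and miR-3605-3p (7 against 0). Known miRNAs called lower were miR-9-3p, miR-191-3p (6 against 12 reads), miR-130b-5p (3 against 9), miR-34c-5p (3 against 8), miR-22-5p (0 against 8) and miR-204-5p (2 against 7). The counting intervals of miR-584-5p, miR-301a-5p, miR-16-2-3p and miR-3605-3p included 1, and those of the other known calls did not. Only 5 of the 26 had 20 reads in a library, and the highest number was 49. In the authors' deposited table miR-92b-5p has p = 0.00913 and an adjusted p of 0.219, and miR-9-3p has p = 0.0140 and an adjusted p of 0.259. The lowest adjusted p of a called known miRNA in the authors' deposited table is 0.126, for miR-22-5p. miR-92a-3p has an adjusted p of 0.00676 in the authors' deposited table and is not called, because its log2 fold change is 0.68. These p-values compare 2 libraries, not the conditions, and rest on a spread assumed rather than measured.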

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

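The tests with known miRNAs alone, with predicted miRNAs at 0 set to 10 reads, with adjusted p under 0.05, with other BCV values, without TMM factors and with any SNHG15 transcript were chosen only after the result was seen. No paired analysis was possible because each group has 1 library. With DESeq2 size factors miR-125b-5p turned from −0.20 to 0.081 and miR-24-3p from −0.21 to 0.064; the intervals of both excluded equality with total reads. Of 156 log2 ratios of named miRNAs under 4 scalings or priors, 131 moved by less than their counting interval, 23 by more and 2 turned. These numbers do not measure robustness. A scaling adds the same constant to every log2 ratio (0.20 with TMM factors, 0.28 with DESeq2 size factors). Whether a ratio then leaves its interval depends on the interval's width, and so on read numbers. Of 36 list medians set against all miRNAs, 30 moved by less than their interval and 6 did not. Those medians were tried only with the larger prior count and the read minimum, since a scaling cannot move them.

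The number of miRNAs at least 2-fold higher in the pulldown, 4, became 2 with a prior count of 5, 75 with no read minimum, 0 with at least 50 reads, 2 at 4-fold, 2 with the whole interval past 2-fold, 2 among known miRNAs alone and 2 with predicted miRNAs at 0 set to 10 reads. The number lower, 5, became 2 with TMM factors, 1 with DESeq2 size factors, 2 with a prior count of 5, 79 with no read minimum, 0 with at least 50 reads, 0 at 4-fold, 0 with the whole interval and 1 among known miRNAs alone. The 2 counted as higher at 4-fold and by the whole interval are predicted miRNAs whose control value of 0 is there taken as a true 0; with 10 control reads their ratio would be 1.10. Higher miRNAs were 44.4% of the 2-fold ones with total reads, 71.4% with TMM factors and 83.3% with DESeq2 size factors. The median of the miR-181 family against all miRNAs, −1.26, became −0.29 with a prior count of 5 and −0.12 with members of 20 reads. That of miR-320, 3.0, became 0.85 and −0.42. With members of 20 reads that of miR-34 and miR-449, −0.81, became 0.29 and that of epithelial miRNAs, −0.43, became 0.52. The last 3 medians changed sign with that minimum, as did the leukocyte median, from −0.13 to 0.35; members with few reads left those medians. With a prior count of 5 the epithelial median became 0.000725, the leukocyte one 0.084 and that of the 14q32 cluster, −0.096, 0.011. Medians not set against all miRNAs changed sign for miR-30, miR-221 and miR-222, and mesenchymal miRNAs with TMM factors, DESeq2 size factors and totals without the 5 most abundant miRNAs, and for miR-15/16, miR-23/27/24 and the 14q32 cluster with DESeq2 size factors alone. Of the 26 miRNAs called in the authors' deposited table, 7 had an adjusted p under 0.01, 10 under 0.05 and 12 were known. A BCV of 0.4 gave 15 calls, 2 of them known, a BCV of 0.2 gave 20, and a run without TMM factors 30. The seed difference of −0.11 was −0.11 with 6-base matches and −0.06 with any transcript. Depth limits all miRNAs under 20 reads; the causes of other changes were not tested.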

Other observations

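The tests of a read minimum, of depth, of near-equal shares and of a trend with GC content as the whole cause were chosen only after the result was seen. miR-218-5p, miR-137, miR-210-3p, miR-196a-5p and the hairpins with differing arms were picked after their values were seen. Lower in the pulldown were also miR-218-5p, carried in introns of SLIT genes (235 against 196 reads, 1.52-fold, 1.25 to 1.84), miR-137 (72 against 60, 1.52-fold, 1.06 to 2.16) and the hypoxia-induced miR-210-3p (42 against 39, 1.69-fold, 1.06 to 2.67). miR-196a-5p, which lies in HOX clusters as miR-10a-5p does, was higher (629 against 284, ratio 1.22, 1.06 to 1.41). Relative to the median of all miRNAs, miR-137 and miR-210-3p were not separated by counting error, while miR-218-5p and miR-196a-5p were.

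In some hairpins the arms lay on opposite sides. miR-27a-5p had a log2 ratio of 1.22 and miR-27a-3p −0.72. miR-378a-5p had −0.75 (30 against 28 reads) and miR-378a-3p 0.38 (95 against 40), while miR-1307-5p had −0.44 and miR-1307-3p 0.48. The intervals of the miR-27a arms did not overlap (0.894 to 8.18 and 0.561 to 0.656), but those of the miR-378a and miR-1307 arms did, and both miR-378a intervals included 1. Over 19 hairpins with both arms at 20 reads, 9 had both arms on one side of the median.

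Predicted miRNAs made up 14 of the 26 calls in the authors' deposited table, and 13 of the 14 had a value of 0 in a library. None of their 100 values lay from 1 to 9 reads (0), against 312 of 714 values of known miRNAs (43.7%), and a candidate explanation is a minimum of 10 reads per library before a prediction is counted. For the 10 with reads in the pulldown alone (11 to 20), an equal share of the shallower control library would give a median of 9.63 reads, and 7 of them under 10, so unequal depth with that minimum may play a part; but 10 of the 12 predicted miRNAs with reads in both libraries and at least 60 in all were lower in the pulldown, and at their median log2 ratio of −0.30 only 3 of the 10 would fall under 10 control reads, which leaves this open. For the 3 with reads in the control alone (11 or 12), depth is argued against, since the pulldown library is the deeper one and an equal share would give a median of 20.0 reads there. With 9 unlisted pulldown reads the counting intervals would still include equality (upper bound up to 1.19), so counting error with that minimum stays open. No biological explanation was tested for these.

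The libraries were nearly equal in miRNA composition, with a Spearman coefficient of 0.967. This is consistent with a background of the resin shared by both libraries, but miRNAs that reached both resins in proportion to their abundance in the lysate would give the same value, and no lysate library was analysed here, so they cannot be told apart.

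Beyond counting error, 56 of 161 miRNAs differed, among them miR-92a-3p, miR-9-5p and miR-29c-3p, and several explanations were tried. Ordinary variation between libraries, which 1 library per resin cannot measure, was not among them and stays open for all of these miRNAs. A trend with GC content of the hairpin as the whole cause is argued against by a Spearman coefficient of −0.0067 with the log2 ratio over the 42 known ones (95% bootstrap interval −0.38 to 0.32). The GC content of the miRNA itself was not measured, and the 42 were selected by the same ratios. A trend with GC content of the miRNA therefore cannot be judged by this test. A smaller effect of GC stays open, with 0.12 over the 133 known miRNAs of 20 reads (shuffles from −0.17 to 0.17). Supply of the hairpin, shared by both arms, gave a coefficient of 0.11 between arms over 19 pairs, within shuffles from −0.46 to 0.45, and stays open. Binding of miRNAs to the MBP-MCP protein itself was not tested. The hypothesis that miRNAs able to pair with SNHG15 were enriched was tested with 6 miRNAs whose seed has a 7-base match, miR-24-3p, miR-345-5p, miR-18a-5p, miR-338-3p, miR-200a-3p and miR-151a-3p. Their median log2 ratio lay −0.11 from that of the others (95% bootstrap interval −0.67 to 0.29, percentile 37.2). No enrichment relative to the others was seen, though the interval leaves room for one. Of the 6, miR-18a-5p, miR-338-3p and miR-200a-3p had fewer than 20 reads in both libraries. All but miR-151a-3p are also on the list of SNHG15 partners, so this is no separate check. With 6-base matches (24 miRNAs) the bootstrap interval was −0.50 to 0.18, and with 7-base matches in any transcript (24 miRNAs) −0.32 to 0.26. These are wider sets of miRNAs, so their intervals do not limit enrichment of the 6 with a 7-base match.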
